A study of Mus musculus with 16 samples.

How the data were processed

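RNA of the ascending aorta and of the aortic valve, the latter dissected as cusp, annulus and root together, was measured in Eln+/+ and Eln+/- mice aged 30 days. There were 16 arrays in 4 groups of 4, given by tissue and genotype. Per the labels, the RNA of each specimen was used separately and nothing was pooled, so each array stands for 1 specimen. The labels do not say whether an aorta and a valve that carry the same number came from the same mouse, and they give no sex. The RNA was amplified from small amounts before labelling, and the study describes a quality check of the RNA without giving its values.

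The authors name RMA for the normalization, per the labels. The deposited values are in the unit ratio, on a linear scale: the signal of a probe set on 1 array relative to the median of that probe set over the 16 arrays. That division is not described in the labels and was read from the values. The median over the arrays was 1, to within 1e-06, in 39827 of the 45101 probe sets, below 1 in 5274 and above 1 in 0, as if a fixed floor had been used in place of a lower median. The lowest of these medians was 0.304. The smallest value was 0.01, held by 14 values in 7 probe sets, and the largest was 58.5. Such ratios keep no signal level, so a filter on dim probe sets and a variance trend with intensity could not be applied, and no statement on absolute expression can be made. No genome build is stated, and no position is given.

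The ratios were put on the log2 scale. The 64 control probe sets were left out and the other 45037 were tested. The platform annotation gives 34945 of them 1 gene, 932 several genes and 9160 no gene. Of the probe sets with 1 gene, 34741 were matched to the reference gene table by Entrez identifier, and 0 symbols had to be updated. In total 18193 genes had a probe set. Because the table holds no level, each gene is shown by its probe set with the highest SD over the 16 arrays, and the same holds for Eln, for which the probe set with the highest mean had been planned.

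A limma model (limma 3.58.1 with statmod 1.5.0 in R 4.3.3, lmFit and eBayes) with 4 group means was fitted to all 16 arrays, with 12 residual degrees of freedom and 3.60 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets and a threshold of 0.05. The comparisons were Eln+/- minus Eln+/+ in each tissue, valve minus aorta in each genotype, and the difference between the genotype effects of the tissues (the interaction). For Eln the exact two-sided permutation test over the 70 assignments of 8 arrays was run too, and the smallest p it can give is 0.0286. The correlation of the genotype effects was compared with 100 random reassignments of genotype within each tissue. The numbers of arrays, 4 in each group, limit the precision.

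In total 39 gene lists were written down. The function lists cover elastic fibre assembly, fibrillar and associated collagens, cartilage-type matrix, proteoglycans, basement membrane, matrix proteases, the TGF-beta, BMP, FGF, Wnt and Notch pathways, valve development transcription factors, cell cycle, vasoactive genes, inflammatory cytokines, interferon response, immediate early genes, heat shock, hypoxia and glycolysis, oxidative phosphorylation, fatty acid oxidation and ribosomal proteins. The marker lists cover smooth, cardiac and skeletal muscle, adipocytes, endothelium, lymphatic endothelium, fibroblasts, macrophages, T cells and thymocytes, B cells, neutrophils and mast cells, erythroid cells, melanocytes, Schwann cells and neurons, mesothelium, airway and thyroid epithelium, and sex-linked genes. Of the 711 listed names 660 were measured. The 38 lists with at least 5 measured members were tested with camera of limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The sex-linked list has 4 measured members and was not tested. The groups, comparisons, tests, lists, alternatives and the rule for named genes were chosen before the data were examined.

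That rule names, for each comparison, Eln; among genes past the threshold whose groups do not overlap, the 8 with the highest rise and the 8 with the deepest fall; where fewer passed in a direction, up to 4 genes of lowest p that did not pass; and the members of lowest p in each list, up to 4 where the list passed and up to 2 where it did not. For the interaction it takes 5 in each direction by p. The text gives a part of the genes so named.

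The fit was tested on simulated data made from the residuals of these arrays with random signs, in 20 simulations with 200 changed probe sets each. For the genotype comparison in the valve it called 51.1% of the probe sets given a log2 change of 1 and 91.3% of those given 2, with 15.25 false calls per simulation. In the aorta these were 53.7%, 92.9% and 21.8, in Eln+/+ tissue 55.0%, 93.4% and 50.55, in Eln+/- tissue 53.8%, 93.1% and 21.1, and for the interaction 19.5%, 77.2% and 10.25. With no change put in, camera at the preset correlation still called lists in all 20 simulations: on average 7.05 in the aorta comparison, 6 in the valve, 5.25 for the tissues in Eln+/+, 9.55 for the tissues in Eln+/- and 7.85 for the interaction. With the estimated correlation the averages were 0.1, 0, 0, 0.1 and 0.

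Alternatives covered robust variances, array weights, median centring and quantile normalization of the deposited values, a fit of only the compared groups, a replicate block, covariates for the 3' to 5' signal of control probe sets, for the Xist minus Y-linked signal and for cardiac muscle or adipocyte genes, a minimum fold of 1.5, the other Eln probe set, and leaving out each array. Added after the data were seen were fits of the probe sets above the floor, without the 2 aorta arrays with cardiac muscle signal, and without the 2 aorta arrays highest in T cell genes. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.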

Results

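The study measured gene expression in the ascending aorta and the aortic valve of mice with 1 inactive allele of Eln (Eln+/-) and of Eln+/+ mice at 30 days of age. Eln encodes elastin, the core protein of elastic fibres. The valve pieces held cusp, annulus and root. Each of the 4 groups, aorta Eln+/+, aorta Eln+/-, valve Eln+/+ and valve Eln+/-, had 4 arrays. Values are log2 ratios of a probe set on 1 array to its median over the 16 arrays, and the median ratio of an array lay between 0.957 and 1.01. Along the first principal component, which held 30.4% of the variance, all 8 aorta arrays had positive and all 8 valve arrays negative scores.

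Eln itself was lower on average in Eln+/- than in Eln+/+ arrays of both tissues. With the Eln probe set of highest SD the log2 value in the aorta was 0.30 ± 0.19 (SD, n = 4) in Eln+/+ and -0.12 ± 0.35 (SD, n = 4) in Eln+/-, a difference of -0.42 ± 0.34 (SE) and a ratio of 0.747. Without aorta Eln+/- replicate 2 that difference was -0.25. In the valve it was -0.44 ± 0.58 (SD, n = 4) in Eln+/+ and -1.71 ± 0.78 (SD, n = 4) in Eln+/-, a difference of -1.27 ± 0.34 (SE) and a ratio of 0.415. The exact permutation p was 0.0571 in each tissue, and the adjusted p of limma was 0.900 in the aorta and 0.395 in the valve, so neither difference passed. The 95% interval of the log2 difference ran from -1.14 to 0.30 in the aorta and from -1.99 to -0.55 in the valve. The other Eln probe set differed by -0.22 in the aorta, with an exact permutation p of 0.0286, the smallest the test can give, and by -0.61 in the valve, with an exact permutation p of 0.143. The difference between the tissues in the Eln effect was -0.85 ± 0.48 (SE), with an adjusted p of 0.687 in limma. In Eln+/+ valve, replicates 1 and 4 had the heart muscle gene Myh6 at 0.96 and 1.00 and Eln at -0.62 and -1.19. Replicates 2 and 3 had Myh6 at 0.45 and 0.68 and Eln at -0.0028 and 0.043. In Eln+/- valve, replicates 1, 2, 3 and 4 had Myh6 at 1.53, 0.94, 1.56 and 1.52 and Eln at -2.03, -1.38, -2.62 and -0.81. There the array lowest in Myh6, replicate 2, was not the one highest in Eln, replicate 4. The genotype difference of Eln was not fitted with the cardiac muscle mean as a covariate, so the part of heart muscle content in it was not tested.

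**Figure D1:**
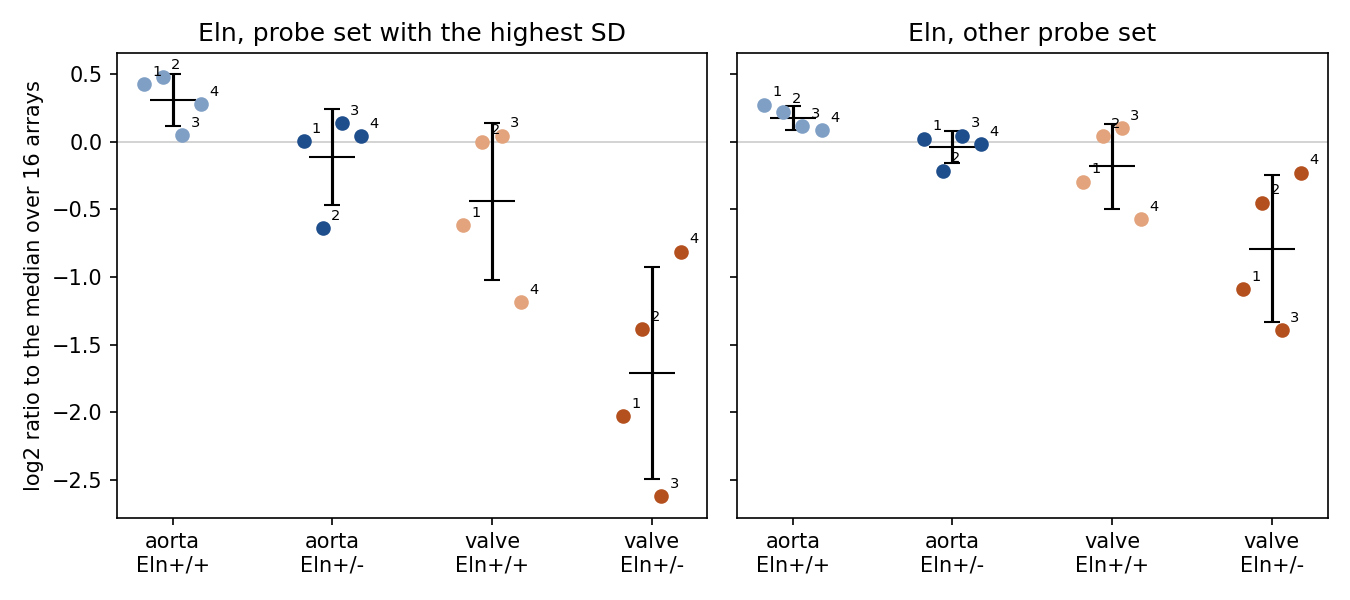
Log2 ratio of both Eln probe sets on each array, by tissue and genotype; points are arrays with their replicate number, the long bar is the group mean and the error bar is 1 SD (n = 4). With the probe set of highest SD (left), Eln+/- replicate 2 lies lowest among the aorta arrays at -0.64, and the group means are 0.30, -0.12, -0.44 and -1.71 from left to right.

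The first question was what the Eln genotype changes in the aorta. No gene passed. Among the genes of lowest p with separate groups, Cp, which encodes the copper carrier ceruloplasmin, was 2.16 ± 0.43 (SE) log2 units higher in Eln+/- aorta, Scaper 0.86, Panx1, a membrane channel gene, 0.59 and Rnf180 1.00, while Entpd7 was at -1.23, Abhd17a at -1.20, Zfp91 at -1.02 and Prss50 at -0.50, with adjusted p of 0.751 to 0.867 in limma. The other probe sets of Abhd17a and Rnf180 had the opposite sign. Of the 38 lists, that of T cells and thymocytes passed in camera at the preset correlation: 12 of 17 measured members were higher and 5 lower, with a median of 0.36 and an adjusted p of 0.00783, and an adjusted p of 0.998 with an estimated correlation. None of its members passed over all genes or adjusted over the list alone. Its members of lowest p were Rag1, the recombinase gene of developing lymphocytes, at 2.37 ± 0.74 (SE), Themis at 1.59, Cd8a at 0.79 and Lat at 0.68.

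These values came from 2 arrays. Rag1 stood at 5.06 in aorta Eln+/- replicate 2 and 3.15 in replicate 4, against -0.54 to 0.68 in the other 6 aorta arrays, and Themis at 3.49 and 2.71. Without these 2 arrays, an alternative chosen after the data were seen, the median of the list was -0.015 and Cd8a stood at -0.0031. Without Eln+/- replicate 2 alone the median was 0.12 and the adjusted p 0.269, in a range of 2.19e-05 to 0.998 over the alternatives. Replicate 2 also held the highest aorta means of the macrophage list, 1.11, and of the erythroid list, 1.06, and the lowest of the smooth muscle list, -0.86.

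Over all 45037 probe sets, 0 passed in the aorta with limma, and 2480 had an unadjusted p under 0.05 where 2252 would by chance. The smallest adjusted p was 0.751. Without Eln+/+ replicate 3 or without replicate 4 of that group, 1 probe set passed. The 1 list past the threshold became 4 without aorta Eln+/- replicate 1, 2 without replicate 2, 3 without replicate 3 and 5 without replicate 4, and 2 without aorta Eln+/+ replicate 1, 4 without replicate 3 and 3 without replicate 4. With the adipocyte mean as a covariate 0 lists passed. The T cell list then had an adjusted p of 0.0999 and a median of 0.35, against 0.36 without the covariate, so its effect hardly moved. The genotypes differed in their sex-linked signal: Xist was high and the Y-linked genes low on all 8 Eln+/- arrays of the tissues and on 2 of the 8 Eln+/+ arrays, aorta replicate 4 and valve replicate 2, with the reverse on the other 6. With that signal, Xist minus the Y-linked genes, as a covariate 8 lists passed in the aorta, 4 higher and 4 lower. By these genes all 8 Eln+/- arrays are of female mice and 6 of the 8 Eln+/+ arrays of male mice, though the labels give no sex. A genotype comparison is thus also a comparison of female with mostly male mice, and this holds for every genotype value given here.

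**Figure D2:**
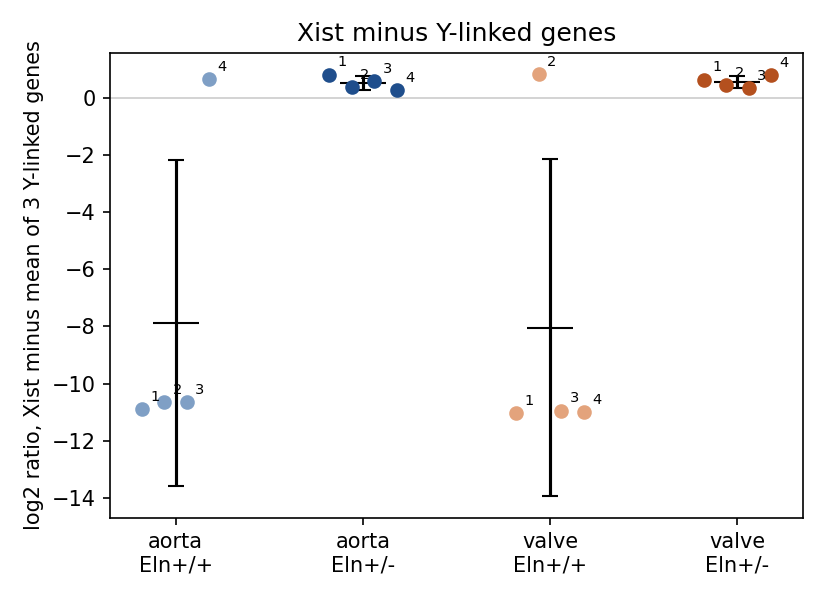
Xist minus the mean of the Y-linked genes Kdm5d, Eif2s3y and Uty on each array (log2), by tissue and genotype; points are arrays with their replicate number, the long bar is the group mean and the error bar is 1 SD (n = 4). Arrays lie either between 0.27 and 0.84, among them all 8 Eln+/- arrays, or between -11.0 and -10.6, where Xist is at the smallest value of the table, 0.01, which sets the size of the gap.

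The same question was asked of the valve. There, genes of energy metabolism and of heart muscle had higher values in Eln+/- and genes of smooth muscle, collagens and elastic fibres had lower values, but no gene passed. These lists passed at the preset correlation, and 0 of them with an estimated correlation or with fry. With the cardiac muscle mean as a covariate the lists of smooth muscle, collagens and elastic fibres turned in sign. The gene nearest to the threshold was Perm1, a regulator of muscle mitochondria, at 1.61 ± 0.21 (SE), 3.05-fold, with an adjusted p of 0.0539 in limma. It was higher in all 4 Eln+/- than in all 4 Eln+/+ valve arrays. Slc25a29, a mitochondrial carrier gene, stood at 1.42, Gpr22 at 1.16 and Prkdc at 0.74, and on the other side Cybrd1, an iron reductase gene, at -1.63, Peli2 at -1.40, Gabre at -1.03 and Nmt2 at -0.89, with adjusted p of 0.193 to 0.295.

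Of the 38 lists 12 passed in camera at the preset correlation, 5 higher and 7 lower in Eln+/- valve, and 0 of them with an estimated correlation or with fry. None of their members passed over all genes. All 20 measured oxidative phosphorylation genes were higher, with a median of 0.80 (adjusted p 2.21e-10, and adjusted p = 0.54 with an estimated correlation), among them the ATP synthase genes Atp5a1 at 0.84 and Atp5o at 0.88 and Uqcrc2 of complex III at 0.94. All 24 cardiac muscle genes were higher, with a median of 0.82 (adjusted p 6.67e-06, and adjusted p = 0.549 with an estimated correlation), such as the natriuretic peptide gene Nppb at 1.49, the creatine kinase gene Ckm at 1.11 and the sarcomere gene Myoz2 at 1.12. Adjusted over the list alone, 2 members passed. The fatty acid oxidation list had 19 of 19 higher with a median of 0.62 (adjusted p 0.000122, and adjusted p = 0.586 with an estimated correlation), including Acads at 0.61 and the nuclear receptor gene Ppara at 1.37. With the Xist minus Y-linked covariate its median was 0.23 (adjusted p 0.552). The skeletal muscle list had 14 higher and 2 lower, with a median of 0.23 (adjusted p 0.00236, and adjusted p = 0.108 with an estimated correlation), with the myosin gene Myh8 at 0.60 and Mybpc2 at 1.23. The cartilage-type matrix list had 16 higher and 4 lower, with a median of 0.38 (adjusted p 0.0102, and adjusted p = 0.586 with an estimated correlation), with the collagen genes Col11a1 at 1.19 and Col9a3 at 0.96 and Chad at 0.97. Without valve Eln+/- replicate 1 its median was 0.26 and its adjusted p 0.429, and its call also ended without valve Eln+/- replicate 4 or without valve Eln+/+ replicate 2 or 3.

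Among the lists lower in Eln+/- valve, smooth muscle contractile genes had 18 of 20 lower, with a median of -0.72 (adjusted p 6.71e-08, and adjusted p = 0.54 with an estimated correlation). Examples were the smooth muscle actin gene Actg2 at -1.42, Mylk, the myosin light chain kinase gene, at -1.08, Ppp1r14a at -1.04 and the smooth muscle myosin gene Myh11 at -0.95, and adjusted over the list alone 1 member passed. Elastic fibre assembly had 14 of 17 lower, with a median of -0.27 (adjusted p 0.00185, and adjusted p = 0.54 with an estimated correlation), with Lox, which crosslinks elastin and collagen, at -0.70, Mfap4 at -0.44 and Mfap5 at -0.40. Adjusted over the list alone 1 passed. Fibrillar collagens had 14 of 20 lower with a median of -0.25 (adjusted p 0.00384, and adjusted p = 0.549 with an estimated correlation), with Col5a1 at -0.57, Col1a2 at -0.52 and Col1a1 at -0.37. TGF-beta genes had 17 of 19 lower with a median of -0.23 (adjusted p 0.00204, and adjusted p = 0.47 with an estimated correlation), with the signal transducer Smad3 at -0.63, Postn at -0.53 and the ligand Tgfb1 at -0.45. Basement membrane genes had 13 of 17 lower with a median of -0.21 (adjusted p 0.0164, and adjusted p = 0.549 with an estimated correlation), with Col4a6 at -0.91 and Col4a5 at -0.58. Wnt genes had 16 of 21 lower with a median of -0.18 (adjusted p 0.0138, and adjusted p = 0.54 with an estimated correlation), with the ligands Wnt5a at -0.97 and Wnt9b at -0.63. Mesothelium and epicardium markers had 12 of 13 lower with a median of -0.58 (adjusted p 0.000741, and adjusted p = 0.549 with an estimated correlation), with the transcription factor Wt1 at -1.21 and Gpm6a at -0.90. Without valve Eln+/- replicate 3 the calls of 5 of these lists ended: the TGF-beta median was then -0.073 (adjusted p 0.103), that of collagens -0.098 (adjusted p 0.348), Wnt -0.087 (adjusted p 0.119), elastic fibre -0.18 (adjusted p 0.0658) and basement membrane -0.17 (adjusted p 0.208). Without valve Eln+/+ replicate 3 the mesothelium median was -0.32 (adjusted p 0.0588), and the basement membrane call ended, as it did without valve Eln+/+ replicate 1. The basement membrane call also ended with the 3' to 5' covariate (median -0.15, adjusted p 0.0987).

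**Figure D3:**
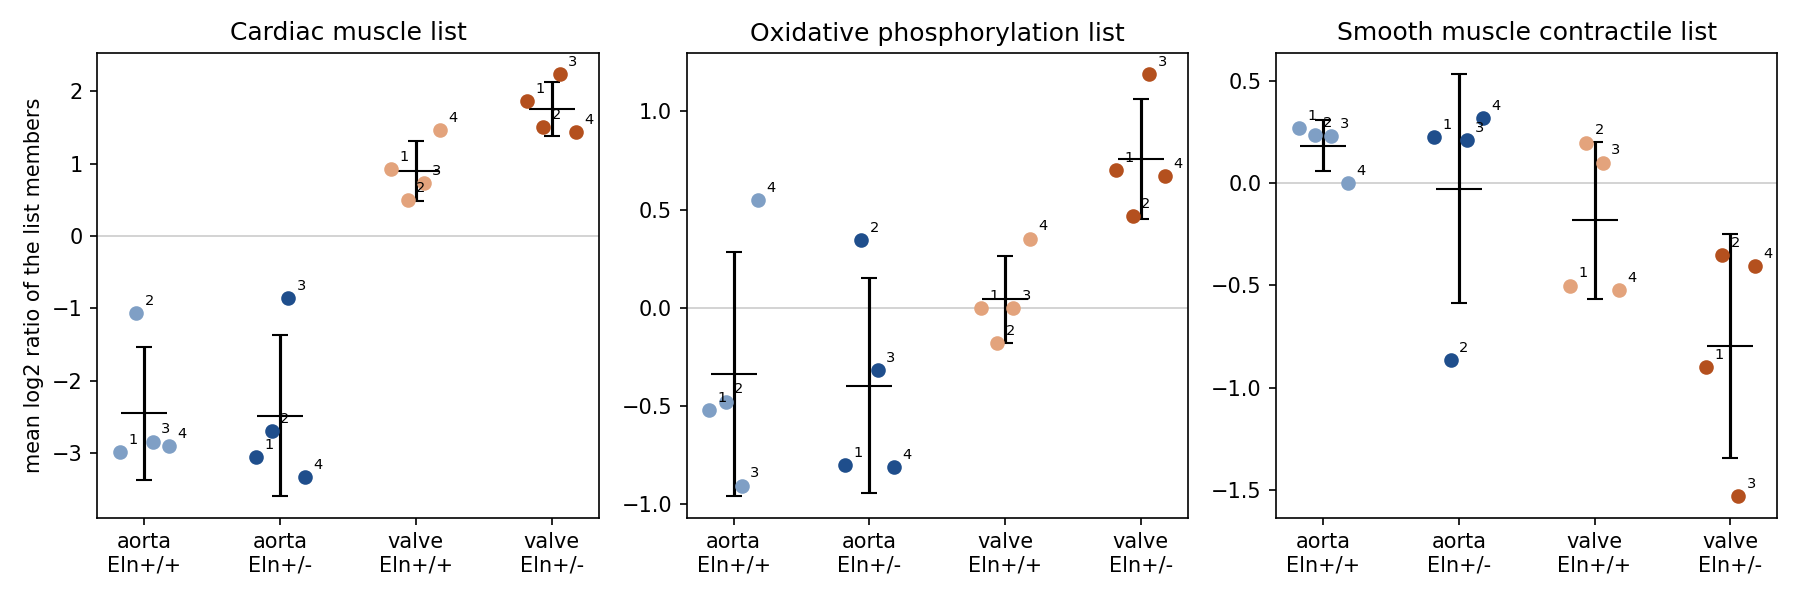
Mean log2 ratio of the measured members of the cardiac muscle, oxidative phosphorylation and smooth muscle contractile lists on each array, by tissue and genotype; points are arrays with their replicate number, the long bar is the group mean and the error bar is 1 SD (n = 4). The cardiac muscle mean is -1.07 in aorta Eln+/+ replicate 2 and -0.86 in aorta Eln+/- replicate 3, with the other aorta arrays between -3.33 and -2.69.

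The amount of heart muscle signal moved with genotype in the valve: the mean of the cardiac muscle list was 0.90 ± 0.42 (SD, n = 4) in Eln+/+ and 1.76 ± 0.37 (SD, n = 4) in Eln+/-, against -2.45 ± 0.92 and -2.48 ± 1.11 in the aorta. With that mean as a covariate in a fit of the 8 valve arrays, 1 list passed, and it was the smooth muscle list with the opposite sign, a median of 0.31 and an adjusted p of 0.0407, in a range of 1.13e-09 to 0.54 over the alternatives. The medians then stood at 0.13 for oxidative phosphorylation, 0.14 for collagens, 0.25 for basement membrane, 0.14 for TGF-beta, 0.041 for elastic fibre, 0.010 for Wnt and 0.19 for mesothelium genes. They stood at 0.44 for cartilage-type, 0.27 for skeletal muscle and 0.27 for fatty acid oxidation genes, against 0.38, 0.23 and 0.62 without the covariate. The single genes Actg2, Myh11, Mylk, Mfap5, Lox, Col1a1, Postn, Col4a6 and Col4a5 also turned in sign. On simulated data with no change, camera at the preset correlation called 6 lists on average in this comparison and up to 12. Over all probe sets 0 passed in limma, with 3873 at an unadjusted p under 0.05 where 2252 would by chance. Without valve Eln+/- replicate 4 there were 11, and without aorta Eln+/+ replicate 1, aorta Eln+/- replicate 3 or valve Eln+/+ replicate 2 there was 1. Without valve Eln+/- replicate 3, 7 lists passed, and 7 of the 12 lost their call when some 1 array was left out. Perm1 passed with array weights, with an adjusted p of 0.043, and the smallest adjusted p of the comparison ran from 0.0334 to 0.374 over the alternatives.

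The next comparison, valve against aorta, asked how the tissues differ, here in Eln+/+ mice. Heart muscle genes, cartilage-type matrix genes and valve transcription factors were higher in the valve. The cartilage-type list did not pass with an estimated correlation. The largest rises among genes with separate groups were in Nppa, the atrial natriuretic peptide gene, at 6.79 ± 0.73 (SE) log2 units, Sln, sarcolipin, at 6.36, the atrial myosin light chain genes Myl7 at 6.33 and Myl4 at 4.94, Prg4, a joint lubricant gene, at 5.28, the potassium channel gene Kcnj3 at 4.99, the iron hormone gene Hamp at 4.94 and the titin gene Ttn at 4.93, with adjusted p of 0.000181 to 0.0255 in limma. Falls among genes with separate groups were smaller: Mia was at -2.18 ± 0.45 (SE), Napepld at -1.40, Arid5b at -1.39, Tes and Mmp17 at -1.38, Slc22a2 at -1.35, Glcci1 at -1.34 and Bpnt1 at -1.28. For Glcci1 1 of 2 further probe sets had the same sign. Eln stood at -0.74 and did not pass, with an adjusted p of 0.405.

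By list, 17 passed at the preset correlation in Eln+/+ mice, that of melanocytes among them. Of the 24 cardiac muscle genes 16 rose, with a median of 3.36 (adjusted p 8.09e-36), and of the 20 cartilage-type genes 8 rose, with a median of 1.27 (adjusted p 9.97e-13), including Comp at 4.02, Ucma at 3.07 and Sox9, a chondrogenic transcription factor, at 1.54. Valve transcription factors had 18 of 20 higher and 4 past the threshold (median 0.53, adjusted p 1.9e-09), including Tbx20 at 2.98, Gata4 at 2.05 and Snai2 at 1.03. The cardiac muscle and valve transcription factor lists also passed with an estimated correlation, with adjusted p = 0.0297 and adjusted p = 0.00161. The other 15 did not, the cartilage-type list with an adjusted p of 0.0658. With fry 6 of the 38 lists passed in Eln+/+ tissue. Adjusted over the list alone, 23 cardiac, 11 cartilage-type and 7 transcription factor genes passed.

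Markers of other cells were higher in Eln+/+ valve too. The valve pieces held heart muscle signal as well. Which cells gave these values, or those of the valve transcription factors, was not tested in either genotype. The lymphatic list had 7 of 8 higher (median 0.73, adjusted p 0.000275, and adjusted p = 0.0658 with an estimated correlation), with rises in Prox1, the lymphatic master regulator, at 3.18 and Flt4 at 1.92. The endothelium list had 15 of 19 higher (median 0.62, adjusted p 0.000113, and adjusted p = 0.296 with an estimated correlation), with a rise in Eng at 1.12. The macrophage list had 19 of 19 higher (median 0.57, adjusted p 1.96e-06, and adjusted p = 0.345 with an estimated correlation), with 0 members past the threshold. The fibroblast list had 10 higher and 6 lower (median 0.57, adjusted p 0.00322, and adjusted p = 0.345 with an estimated correlation), with a rise in Tcf21 of 1.34 and in Lum of 1.12 and a fall in Mfap5. The proteoglycan list had a median of 0.11 (adjusted p 0.017, and adjusted p = 0.196 with an estimated correlation), with Fmod, fibromodulin, at 2.52. The Wnt list had a median of 0.18 (adjusted p 0.00347, and adjusted p = 0.256 with an estimated correlation), with rises in Wnt9b of 1.87 and in the Wnt target Axin2 of 1.60. The inflammatory list had a median of 0.23 (adjusted p 0.00672, and adjusted p = 0.198 with an estimated correlation), with the adhesion molecule Vcam1 at 1.60. The matrix protease list had a median of 0.00 and a mean of 0.25 (adjusted p 0.0432, and adjusted p = 0.317 with an estimated correlation), with rises in Mmp3 of 1.69 and in Timp1 of 1.15. The lists of oxidative phosphorylation with a median of 0.40 (adjusted p 0.000437), cell cycle with 0.31 (adjusted p 0.00181) and FGF genes with 0.29 (adjusted p 0.0189) passed without any member past the threshold, at adjusted p of 0.63, 0.296 and 0.087 with an estimated correlation. Without aorta Eln+/+ replicate 3 the oxidative phosphorylation median was 0.19 (adjusted p 0.0807). Without aorta Eln+/+ replicate 4 the FGF list had an adjusted p of 0.0572 and the proteoglycan list, at a median of 0.072, one of 0.0834. Without aorta Eln+/+ replicate 1 the proteoglycan median turned to -0.0066, so the sign of that median rests on 1 array. The protease call ended in 5 of the fits that left out 1 array.

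Lists lower in Eln+/+ valve were those of adipocytes, with 15 of 17 lower and a median of -0.72 (adjusted p 0.00181, and adjusted p = 0.478 with an estimated correlation), and of smooth muscle, with 18 of 20 lower and a median of -0.63 (adjusted p 0.00497, and adjusted p = 0.63 with an estimated correlation). With the 3' to 5' covariate the smooth muscle median was -0.37 (adjusted p 0.159). None of those lower members passed: Smtn was at -0.93 and Myh11 at -0.91. The members of the smooth muscle list that did pass rose, Casq2 at 3.14 and Des at 1.48, and both are known as heart muscle genes as well. The other Des probe set had the opposite sign. The aorta adipocyte means differed widely, from -0.56 to 2.00 in Eln+/+, with the highest in replicate 4. Without that array the adipocyte list had a median of -0.35 and an adjusted p of 0.298, in a range of 3.41e-06 to 0.478 over the alternatives.

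In all, 426 of 45037 probe sets passed in Eln+/+ mice, 382 higher and 44 lower in the valve. They covered 240 genes, 217 higher and 23 lower. The count was 242 without aorta Eln+/+ replicate 1, 246 without aorta replicate 3, 173 without valve replicate 1, 184 without valve replicate 4 and 692 after quantile normalization. Paired by replicate number within these groups, 48 passed.

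In Eln+/- mice the same tissue contrast gave higher heart muscle, energy metabolism and cartilage-type genes in the valve and lower smooth muscle genes. Of these lists only that of heart muscle also passed with an estimated correlation. Among genes with separate groups, the rises were led by Nppa at 6.68 ± 0.73 (SE), Sln at 6.45, Myl7 at 6.40, Kcnj3 at 6.24, Ttn at 6.03, Hamp at 5.99, Smpx at 5.91 and Smyd1 at 5.91, all of them past the threshold, with adjusted p of 0.000124 to 0.00218 in limma. The falls were led by the BMP receptor gene Bmpr1b at -3.35 ± 0.46 (SE), Serpina1b at -3.14, the neural adhesion gene Ncam1 at -2.77, the thyroid hormone activating enzyme gene Dio2 at -2.66, the progesterone receptor gene Pgr at -2.65, Tktl1 at -2.52, Hoxa3 at -2.46 and Mark1 at -2.41. The probe set of Serpina1b had a median below the floor. Eln fell by 1.60 on the log2 scale, with an adjusted p of 0.0110, but its other probe set stood at -0.75 and did not pass, with an adjusted p of 0.0576. With the 3' to 5' covariate the first did not pass either, with an adjusted p of 0.0803.

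By list, 15 passed at the preset correlation in Eln+/- mice, again with melanocytes among them. Of 24 cardiac muscle genes 23 rose, with a median of 4.45 (adjusted p 1e-32), of 20 oxidative phosphorylation genes 11 rose, with a median of 1.11 (adjusted p 2.68e-13), and of 20 cartilage-type genes 11 rose, with a median of 1.60 (adjusted p 9.72e-11). Examples are Ndufa5 of complex I at 1.66 and Atp5o at 1.55, and Comp at 3.83, Ucma at 3.71, Col9a3 at 3.04 and Sox9 at 2.07. The smooth muscle list had 18 of 20 lower and a median of -1.09 (adjusted p 5.35e-07), with 8 that fell, such as Myh11 at -1.48 and Ppp1r14a at -1.25, and with Casq2 and Des up by 4.19 and 2.73. Valve transcription factors had 6 members that rose (median 0.47, adjusted p 6.23e-06), among them Tbx20 at 3.29, Tbx5 at 3.09 and Gata4 at 2.11. The cardiac muscle and valve transcription factor lists also passed with an estimated correlation, with adjusted p = 0.0411 and adjusted p = 0.0162. The other 13 did not, among them oxidative phosphorylation, cartilage-type, smooth muscle and melanocyte genes with adjusted p of 0.302, 0.1, 0.403 and 0.1. With fry 10 of the 38 lists passed in Eln+/- tissue, and the smooth muscle list, at an adjusted p of 0.0865, did not. Adjusted over the list alone, 23 cardiac, 18 oxidative phosphorylation, 13 cartilage-type and 17 lower smooth muscle genes passed.

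The elastic fibre list in Eln+/- tissue had a median of -0.50 (adjusted p 0.0419, and adjusted p = 0.476 with an estimated correlation). Without valve Eln+/- replicate 3 the median was -0.25 (adjusted p 0.108) and with the 3' to 5' covariate -0.18 (adjusted p 0.356), and the call also ended without aorta Eln+/- replicate 1 or 3 and without valve Eln+/+ replicate 1 or 2. In the list 4 members fell, Lox at -1.96, Eln by the first of its 2 probe sets only, Mfap5 at -1.41 and Mfap4 at -0.90, and 2 rose, of which Fbn2, fibrillin 2, stood at 3.02. The fatty acid oxidation list had a median of 0.61 (adjusted p 0.000146, and adjusted p = 0.547 with an estimated correlation), with rises in Fabp3 of 2.84 and in Ppargc1a of 1.99. Basement membrane genes had a median of -0.36 (adjusted p 0.0114, and adjusted p = 0.476 with an estimated correlation), with falls in Col4a6 to -1.51 and in Col4a5 to -1.09. That call ended without aorta Eln+/- replicate 1 (adjusted p 0.0537) or 3 (adjusted p 0.0502) and with the 3' to 5' covariate (median -0.24, adjusted p 0.258). Skeletal muscle had a median of 0.27 (adjusted p 0.0197, and adjusted p = 0.1 with an estimated correlation), with Acta1 up by 2.06 and Mybpc2 by 1.82. Endothelium had a median of 0.72 (adjusted p 0.00398, and adjusted p = 0.476 with an estimated correlation), with rises in Flt1 of 1.46 and Eng of 1.24 and a fall in Erg to -0.90. The lymphatic list had a median of 0.72 (adjusted p 0.0287, and adjusted p = 0.302 with an estimated correlation), with Prox1 up by 4.12 and Flt4 by 1.56. Without aorta Eln+/- replicate 4 its median was 0.47 (adjusted p 0.147), and the call also ended without aorta replicate 1 or valve replicate 4 of that genotype. Macrophage markers had a median of 0.62 (adjusted p 0.00405, and adjusted p = 0.591 with an estimated correlation), with Cd14 up by 1.11. Without aorta Eln+/- replicate 4 the macrophage median was 0.29 (adjusted p 0.139). Adipocyte markers had a median of -0.90 (adjusted p 0.00519, and adjusted p = 0.547 with an estimated correlation), with Dio2 and Scd1, at -1.66, past the threshold. T cell markers had a median of -0.24 (adjusted p 0.0103, and adjusted p = 0.542 with an estimated correlation), with Lat at -0.95. Without aorta replicate 2 the T cell list had a median of -0.11 and an adjusted p of 0.15, in a range of 0.000165 to 0.542 over the alternatives. The adipocyte list then had a median of -0.63 and an adjusted p of 0.0580, in a range of 0.000547 to 0.547.

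**Figure D4:**
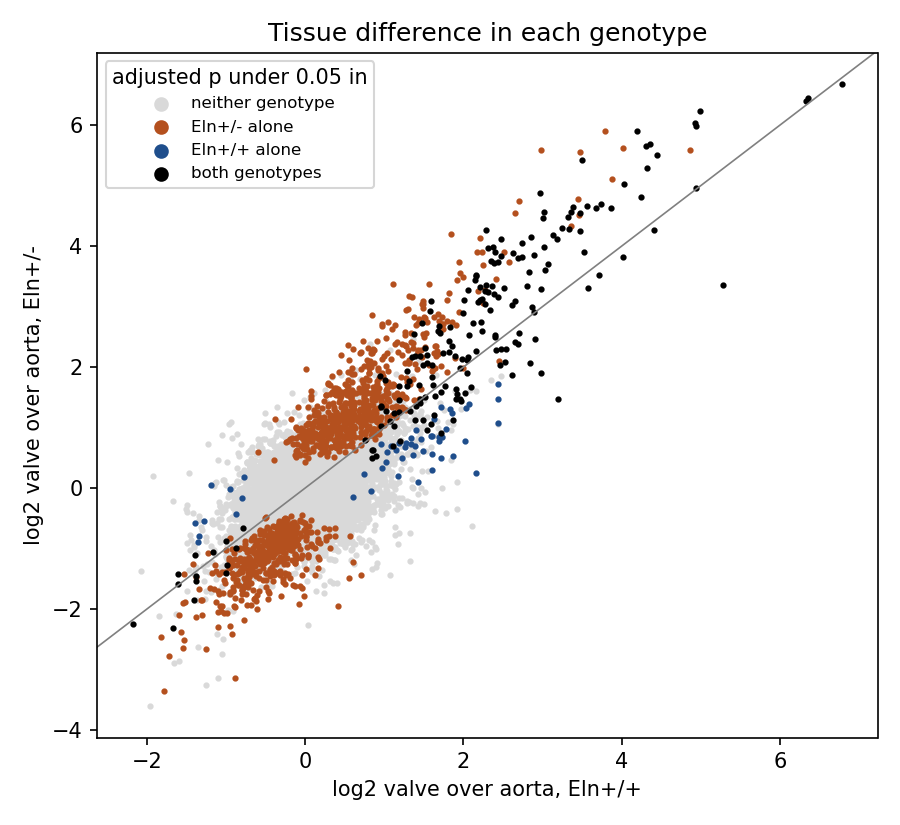
Valve minus aorta log2 difference of 18193 genes in Eln+/+ mice (horizontal) and Eln+/- mice (vertical); each point is a gene, coloured by the genotype in which its adjusted p passed, and the line marks equal differences. In Eln+/+ mice 240 genes passed, in Eln+/- mice 1285, and 188 passed in both.

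Of 45037 probe sets 2615 passed in Eln+/- mice, 1473 higher and 1142 lower in the valve, from 802 higher and 483 lower genes. The count was 1600 without aorta Eln+/- replicate 1, 1617 without aorta replicate 4, 1640 without valve replicate 1 and 1366 without valve replicate 3. It was 1070 with the 3' to 5' signal of the control probe sets as a covariate, 1638 without the 2 aorta arrays with cardiac muscle signal, 1602 with only these groups in the fit and 956 paired by replicate number.

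The tissue contrasts of the genotypes were compared by their overlap. The genotypes shared 311 probe sets with the same sign, 285 higher and 26 lower, where independent lists of these sizes would share 13.6, and 0 passed with opposite signs. Of the 426 probe sets past the threshold in Eln+/+ mice, 416 had the same sign in Eln+/- mice. The overlap was 184 without aorta Eln+/+ replicate 1, 186 without aorta replicate 3, 146 without valve replicate 1, 150 without valve replicate 4 and 478 after quantile normalization. More probe sets passed in Eln+/- than in Eln+/+ mice, but the difference itself was not beyond random regroupings, 11 of 100 of which gave one as large.

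The interaction asked whether the Eln genotype acts differently in the valve and the aorta. No gene passed. The genes of lowest p were Perm1 at 1.95 ± 0.30 (SE), Plpp7 at 1.53, Higd1b at 1.31 and Pllp, a myelin membrane gene, at 0.86 on the side higher in the valve, and Rwdd1 at -2.54, Lonrf3 at -1.82, Gabre at -1.46 and Zfp626 at -1.35 on the other, with adjusted p of 0.338 to 0.619 in limma. The other Rwdd1 probe set had the opposite sign. Of the 38 lists 9 passed at the preset correlation, and 0 with an estimated correlation or with fry. Oxidative phosphorylation, with 20 of 20 members higher in the valve effect, had the lowest adjusted p (1.41e-06, and adjusted p = 0.767 with an estimated correlation). Wnt genes had 17 of 21 lower (adjusted p 0.00238, and adjusted p = 0.504 with an estimated correlation). The lists of fatty acid oxidation, cardiac muscle and mesothelium had the same adjusted p as Wnt genes at the preset correlation. Without valve Eln+/+ replicate 3, 5 lists passed, and 7 of the 9 lost their call when some 1 array was left out. In limma 0 probe sets passed and 3477 had an unadjusted p under 0.05.

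Across 18193 genes, which are not independent replicates, the genotype effects of the aorta and of the valve had a Pearson correlation of 0.00891 and a Spearman correlation of -0.0358. In 91 of 100 random reassignments of genotype the Pearson value was as large in size, a permutation p of 0.911. The effects had the same sign in 47.4% of the genes.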

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

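The covariate fits, the estimated correlation, fry and the interaction tests in this part were planned. How the fits were read as tests of explanations, the fit without the 2 aorta arrays with cardiac muscle signal and the regroupings of arrays were chosen after the results were seen, and so was the test on further thymus genes, which was set before their values were looked at.

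In Eln+/- valve, energy and heart muscle lists stood higher and smooth muscle, collagen and elastic fibre lists lower, by 12 calls at the preset correlation of which 0 remained with an estimated correlation or with fry. With the 3' to 5' signal of the control probe sets as a covariate, 11 of the 12 lists passed in the same direction, and the basement membrane list did not. These calls are at the preset correlation, where simulated data with no change gave up to 12 lists. They are thus only weak evidence against RNA quality as the whole cause. Valve Eln+/- replicate 3 had the lowest 3' to 5' value, -0.34, and without it calls of lower lists ended, as given above. With the cardiac muscle mean as a covariate 0 of the 12 did, so different shares of heart muscle and vessel wall in the dissected pieces may account for the shifts: the oxidative phosphorylation median went from 0.80 to 0.13, and the median error of a valve difference widened from 0.188 to 0.287, so calls ended through smaller effects and wider errors, and for the lists of cartilage-type genes, at 0.38 before and 0.44 after, and of skeletal muscle, at 0.23 and 0.27, the effect was no smaller. None of the 24 cardiac markers is in another list, the values hold no level from which to count those the valve itself expresses, and the list's own value says nothing here because it is the covariate. With the Xist minus Y-linked covariate 7 of the 12 passed. The lists that did not had medians of 0.23 for fatty acid oxidation, -0.14 for collagens, -0.17 for elastic fibre, -0.088 for Wnt and 0.23 for skeletal muscle. Without it these were 0.62, -0.25, -0.27, -0.18 and 0.23, so the skeletal muscle effect hardly moved. Only 1 valve and 1 aorta array part the sex-linked profile from the genotype, so these cannot be told apart. An effect of the Eln genotype on the valve itself stays open and untested.

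The tissue contrast gave 2615 probe sets in Eln+/- and 426 in Eln+/+ mice, a difference of 2189. Without the 2 aorta arrays with cardiac muscle signal the ratio of these counts was 4.37, and with the 3' to 5' covariate 3.55. Both are lower than the ratio of 2615 to 426, so a part of the difference may go with each. With the 3' to 5' covariate the Eln+/- count stayed the higher one, which argues against RNA quality as the whole cause. The 2 arrays left out came from both genotypes, so leaving them out could hardly test heart muscle RNA in them as the cause. In the valve the cardiac muscle mean was 0.90 in Eln+/+ and 1.76 in Eln+/-. The part of that difference in the counts was not tested. Of 100 random regroupings 11 gave a difference as large, up to 3217, so chance cannot be excluded, and a difference by genotype stays open.

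The T cell and thymocyte list stood higher in Eln+/- aorta at the preset correlation, through replicates 2 and 4, with an adjusted p of 0.998 with an estimated correlation and 0.972 with fry. These 2 arrays were picked by this list, so its members, Rag1 among them, cannot test why. Over 17 further genes of thymus and T cells in none of the lists, the median difference of these 2 from the other 6 aorta arrays was 0.30, with 11 genes higher. Single genes ran from -0.19 for Ccl25 to 1.87 for Bcl11b. Yet 4 of the 28 pairs of aorta arrays, this one included, gave a median as high, up to 0.46. Thymus tissue in the 2 dissected pieces thus cannot be told apart from other differences between arrays, with 8 aorta arrays and no signal level for the abundant thymus genes. An effect of genotype on such cells in the aorta was not tested.

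Regroupings of the 8 arrays of a comparison into 35 splits counted how often a result as large came up, the real one included. For the tissue contrast this was 1 of 35 in Eln+/+ mice (426 probe sets, at most 1 in another split) and 1 of 35 in Eln+/- mice (2615, at most 97). That is the lowest share that 35 splits can give. The other splits put aorta and valve arrays in 1 group, so a tissue difference widens the error there and leaves few calls. The splits alone thus do not exclude chance. In the simulations false calls averaged 50.55 in Eln+/+ and 21.1 in Eln+/- tissue, well under the real counts. The overlap of 311 was reached in 1 of 100 regroupings, with at most 0 in the others, but regrouped arrays gave hardly any calls that could overlap, so this repeats the 2 counts and does not test whether the genotypes share them. For the lists it was 1 of 35 for the tissues in Eln+/+ (17, at most 13), the lowest share that 35 splits can give. Simulated data with no change gave up to 12 lists there, and 2 of the 17 passed with an estimated correlation. Chance is thus not excluded for the other lists. In the valve genotype comparison it was 1 of 35 as well (12 lists, at most 11 otherwise), but simulated data with no change gave up to 12, so chance is not excluded for these lists. It was 8 of 35 for the tissue lists in Eln+/- (15, at most 18) and 33 of 100 for the interaction lists (9, at most 15), so chance cannot be excluded there. In the aorta genotype comparison all 35 splits gave as many probe sets (0, at most 8) and all 35 as many lists (1, at most 16), in the valve all 35 gave as many probe sets (0, at most 11), and for the interaction all 100 did (0, at most 2). Many splits of the aorta arrays called more lists than the genotype, and simulated aorta data with no change gave up to 15. Those data were made from the residuals of these same arrays. They thus cannot tell whether a structure of the arrays lies behind this.

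In 24 of 496 groups of 4 arrays, 1 array stood apart from the other 3 beyond Dixon's 95% limit, where chance gives 24.8 at 1 in 20. Among the list means, aorta Eln+/+ replicate 4 stood apart in collagens at -0.40 and in smooth muscle at 0.0014, aorta Eln+/- replicate 2 in smooth muscle at -0.86, aorta Eln+/+ replicate 2 in cardiac muscle at -1.07, valve Eln+/- replicate 3 in skeletal muscle at 0.49, valve Eln+/- replicate 4 in adipocytes at 0.0040 and valve Eln+/+ replicate 3 in airway and thyroid epithelium at 0.12.

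Among genes, aorta Eln+/+ replicate 2 stood apart in Casq2 at -0.68 and Kcnj3 at -1.06. Aorta Eln+/- replicate 1 did so in Ncam1 at 0.085 and Pgr at 1.40, replicate 2 in Eln at -0.64 and Mark1 at -0.24, and replicate 4 in Bmpr1b at 1.96 and Col8a1 at -1.97. In Eln+/+ valve it was replicate 1 in Gpr22 at 0.67, replicate 2 in Wnt5a at 1.80, and replicate 4 in Mlana at 2.41 and Postn at -0.51. In Eln+/- valve it was replicate 2 in Smyd1 at 1.62, replicate 3 in Col11a1 at 0.81, Col8a2 at 0.33 and Des at 1.75, and replicate 4 in Nppa at 0.86.

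The genotype effect differed between valve and aorta in 9 lists by the interaction test at the preset correlation, and in 0 with an estimated correlation. The medians of the difference, valve effect minus aorta effect, were 1.01 for cardiac muscle, 0.84 for oxidative phosphorylation, 0.71 for fatty acid oxidation, 0.33 for skeletal muscle, -0.30 for collagens, -0.30 for Wnt, -0.33 for TGF-beta, -0.52 for smooth muscle and -0.58 for mesothelium genes, with adjusted p of 1.41e-06 to 0.0459, and of 0.504 to 0.767 with an estimated correlation. In 7 of the 9 the call ended when some 1 array was left out. The cardiac muscle median was 0.35 (adjusted p 0.0845) without aorta Eln+/+ replicate 2, that of fatty acid oxidation 0.33 (adjusted p 0.288) without aorta Eln+/+ replicate 4, those of collagens -0.091 (adjusted p 0.456) and smooth muscle -0.29 (adjusted p 0.241) without valve Eln+/- replicate 3, and that of mesothelium -0.28 (adjusted p 0.0708) without valve Eln+/+ replicate 3.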

How the results depend on the processing

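The alternatives for probe sets above the floor and without named pairs of aorta arrays were chosen after the data were seen; the others were planned. The mean above the 60th percentile and the intensity trend had no signal level to work on and were not run, and the fit already had no filter. What signal over background limits cannot be told from ratios. Centring and quantile normalization moved the median log2 difference of each comparison by less than 0.1.

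Probe set counts: the interaction stayed at 0 in all alternatives. The genotype count in the aorta was 0 to 1 when each array was left out, and 0 otherwise. In the valve it was 1 with array weights, 1 above the floor, 1 without the 2 aorta arrays with cardiac muscle signal, and 0 to 11 when each array was left out. The tissue count in Eln+/+, 426, was 692 with quantile normalization and 173 to 553 when each array was left out. In Eln+/-, 2615, it was 1070 with the 3' to 5' covariate, 1602 with only the compared groups, 1638 without the 2 aorta arrays with cardiac muscle signal, and 1366 to 3457 when each array was left out. The overlap, 311, was 478 with quantile normalization and 146 to 410 when each array was left out.

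Replicate block: paired by number within the compared groups, 48 probe sets passed in Eln+/+ and 956 in Eln+/- tissue. With the number as a fixed term in all arrays there were 297 and 2041, and with genotype and number as a random block 446 and 2680, at a consensus correlation of 0.0105. For Eln the paired exact permutation p was 0.25 in both tissues, where the smallest that test can give with 4 pairs is 0.125, so it could not pass. It paired each Eln+/- array with the Eln+/+ array of the same number. These are different mice that no label links, so that pairing has no basis in the design. Aorta and valve arrays of 1 genotype were also correlated by their deviations from the group means. With the same number these correlations ran from -0.034 to 0.052 in Eln+/+ and from -0.040 to 0.040 in Eln+/-. With different numbers they ran from -0.083 to 0.107 and from -0.103 to 0.116, so the numbers do not show pairs.

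List counts: with an estimated correlation 0 passed for genotype in the aorta, 0 in the valve, 2 and 2 for the tissues in Eln+/+ and Eln+/- and 0 for the interaction; with fry 0, 0, 6, 10 and 0. In the aorta, 1 in the planned test, there were 8 with the Xist minus Y-linked covariate, 0 with the adipocyte covariate, 4 without the 2 aorta arrays highest in T cell genes, and 1 to 5 when each array was left out. In the valve, 12, there was 1 with the cardiac muscle covariate, and 7 to 14 when each array was left out. For the interaction, 9, leaving out each array gave 5 to 11.

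Turned in sign: with the cardiac muscle covariate in the valve, Actg2 stood at 0.22, Myh11 0.12, Mylk 0.27, Mfap5 0.067, Lox 0.46, Col1a1 0.051, Postn 0.25, Col4a6 0.41 and Col4a5 0.26, and the lists of collagens 0.14, basement membrane 0.25, TGF-beta 0.14, smooth muscle 0.31, elastic fibre 0.041, Wnt 0.010 and mesothelium 0.19. For the tissues in Eln+/+, the protease list, with a median of 0.0011, stood at -0.00041 with the Xist minus Y-linked covariate and at -0.021 above the floor, and the proteoglycan list, at 0.11, ran from -0.0066 to 0.21 when each array was left out. Without the 2 aorta arrays highest in T cell genes, Cd8a stood at -0.0031 and the T cell list at -0.015. The correlation of genotype effects, 0.00891, was -0.0358 by Spearman, -0.0027 above the floor, and -0.0448 to 0.0557 when each array was left out.

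The aorta difference of Eln was -0.22 with the other probe set, with an exact permutation p of 0.0286 and an adjusted p of 0.920 in limma.

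Of the named genes past the threshold, 12 of 44 in Eln+/+ and 37 of 66 in Eln+/- stayed past it in all alternatives. Fewer arrays, wider errors or a changed scale go with these changes by construction, and otherwise the cause was not tested.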

Other observations

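Pigment cell genes were higher in the valve in both genotypes. The melanocyte list had 10 of 11 measured members higher in each, with a median of 0.78 in Eln+/+ (adjusted p 3.59e-05, and adjusted p = 0.0658 with an estimated correlation) and 0.40 in Eln+/- (adjusted p 0.000146, and adjusted p = 0.1 with an estimated correlation). Dct, a melanin synthesis enzyme gene, rose by 2.29 ± 0.48 (SE) log2 units in Eln+/+ and 3.36 in Eln+/-, Mlana by 2.05 and 2.17, and Tyrp1 by 2.56 in Eln+/-. Nerve markers had members that rose without a call for the list: Cdh19, a Schwann cell cadherin gene, by 1.90 in Eln+/+, and Dbh, the noradrenaline synthesis enzyme gene, by 2.25 and Gfra3 by 0.90 in Eln+/-. That list of Schwann cells and neurons had an adjusted p of 0.144 in Eln+/+ and 0.0686 in Eln+/-.

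Further genes differed between the tissues in lists that did not pass. Among the collagens, Col8a1 rose in the valve by 2.91 ± 0.36 (SE) in Eln+/+ and 2.46 in Eln+/-, and Col8a2 by 2.41 and 2.28. The list had a median of -0.14 and a mean of 0.27 in Eln+/+, and of -0.40 and 0.04 in Eln+/-, with adjusted p of 0.355 and 0.307. Bmp2, a bone morphogenetic ligand gene, rose by 0.96 in Eln+/+ and 1.02 in Eln+/-, Bmpr1a fell by 0.79 in Eln+/+ with 4 of 5 further probe sets of the same sign, and the osteogenic transcription factor gene Dlx5 fell by 2.27 in Eln+/-. The BMP list had adjusted p of 0.355 and 0.648. In the Notch list, the target gene Hey1 rose by 1.13 and Hey2 fell by 1.11 in Eln+/- (list adjusted p 0.465). In the vasoactive list, Ace, the angiotensin converting enzyme gene, fell by 0.88 and Gucy1b1, a nitric oxide receptor subunit gene, by 1.14 in Eln+/- (list adjusted p 0.337). In the hypoxia and glycolysis list Ndrg1 rose by 1.48 in Eln+/+, and Egln3 by 1.80 and Aldoa by 1.04 in Eln+/- (list adjusted p 0.108 and 0.0593). Among proteoglycan genes Gpc1 rose by 2.29 and the hyaluronan synthase gene Has2 by 1.38 in Eln+/- (list adjusted p 0.393).

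Adjusted over the list alone, 3 Notch genes were lower in Eln+/- aorta, and 1 vasoactive gene was higher and 1 lower in Eln+/- valve, while their lists had adjusted p of 0.35 and 0.316. Of the 13 lists that passed in no comparison, the others had these adjusted p for genotype in the aorta, genotype in the valve, tissue in Eln+/+ and tissue in Eln+/-. They were 0.331, 0.316, 0.151 and 0.307 for interferon response, 0.942, 0.316, 0.702 and 0.704 for immediate early genes, and 0.331, 0.875, 0.551 and 0.466 for heat shock. They were 0.48, 0.776, 0.866 and 0.288 for ribosomal proteins, 0.851, 0.316, 0.46 and 0.811 for B cells, and 0.942, 0.656, 0.551 and 0.325 for neutrophils and mast cells. They were 0.995, 0.252, 0.282 and 0.959 for erythroid cells, and 0.436, 0.699, 0.551 and 0.465 for airway and thyroid epithelium.

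The heart muscle signal in the aorta arrays was uneven by gene. The myosin gene Myh6 stood at -0.65 in aorta Eln+/+ replicate 2 and -0.73 in aorta Eln+/- replicate 3, against -5.94 to -4.18 in the other 6. Nppa stood at -4.66 in the former, -2.40 in the latter and -2.64 in aorta Eln+/- replicate 2. In the sex-linked list, adjusted over the list alone, 1 gene was higher and 3 were lower in Eln+/- than in Eln+/+ in each tissue. The Eln+/+ arrays with number 2, and those with number 4, held a different sex-linked profile in aorta and valve, so these numbers do not join specimens of 1 mouse. The highest correlation of any 2 arrays was 0.613, and the smallest mean absolute log2 difference of 2 arrays of a group was 0.318, so no 2 arrays held the same values.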
